A study of Mus musculus with 6 samples.

How the data were processed

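Total RNA from the left ventricle of adult male C57BL/6 mice was measured on 6 Affymetrix expression arrays, 3 from mice lacking the muscle-restricted coiled-coil protein MURC and 3 from wild-type mice. MURC, now named cavin-4 and encoded by Cavin4, is a muscle protein of caveolae, the small flask-shaped pits of the cell membrane. Per the labels' protocols, RNA was extracted with TRIzol and 100 ng of total RNA was labelled with biotin. The knockout samples were labelled as 11, 11 and 13 weeks of age and the wild-type samples as 13, 13 and 12 weeks.

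The authors deposited 1 table of log2 expression values, with 35556 probe sets and 1 column per array. The submitters' processing notes name MAS5, without its role or version. Summarization, background correction and scaling between arrays are not given in the sources used here, nor is the genome build of the array design. That the values are log2 was settled from the values themselves, which ran from 0.46 to 13.72 and would exceed the range of a scanner on a natural or decimal logarithm. The deposited values were used as they stand, because the medians of the 6 columns lay between 4.60 and 4.71. These medians alone do not settle whether the arrays were on a common scale, and the counts of changed probe sets given below depended on further normalization.

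Probe sets were named through the platform annotation. It gave 1 gene symbol to 21789 probe sets and several to 1621, and it did not list the other 12146, which are unnamed here. Symbols were updated through the gene identifier in the RefSeq table of GRCm38.p6, which matched 21698 of the probe sets with 1 symbol. That table was used only for names, RNA classes and which genes lie near each other. The files do not mark control probe sets, so none was left out in the main test. No gene was named from a probe set with several symbols.

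Genotypes were compared in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), as knockout minus wild type, two-sided, over probe sets whose mean over the 6 arrays was at or above the 30th percentile. That filter, at a log2 value of 3.45, kept 24898 probe sets, of which 17934 were listed in the annotation and 6964 were not, covering 15298 named genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A looser count took an unadjusted p under 0.05 with at least a 1.5-fold change. Values are given as mean ± SD over 3 arrays, and every fold change is a difference of log2 signals, which background can compress for dim probe sets. The number of arrays limits the precision.

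For gene lists, the probe set with the highest mean stood for its gene. The 40 lists, with 899 genes in all, were tested with camera at a preset correlation of 0.01, which asks whether a list's genes moved relative to all other genes. Its p-values were adjusted over the 40 lists, and Cavin4 was left out. The same lists were run with a correlation estimated from the residuals and with fry, and the members were also adjusted over the list alone. Of the list genes, 120 were not tested, 88 of them because no named probe set carried the symbol. Genes within 10 Mb of Cavin4 were compared with all others by Fisher's exact test. The gene lists, tests, filters and the rule for named genes were fixed before the data were examined.

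The genes named are Cavin4 and the measured caveola proteins, the 12 genes per direction with the largest change among non-overlapping probe sets past the threshold, and up to 4 members of each list described with the smallest p. Where fewer than 12 passed, the places were filled by non-overlapping probe sets with at least a 1.5-fold change in order of unadjusted p. Predicted genes, microRNAs, small nucleolar RNAs and olfactory or vomeronasal receptors were left out of the 12. The rule took 1 probe set per gene without saying which. The probe set with the highest mean was taken, as for the lists, so a gene that changed only in another probe set is not among the 12. Members past the threshold adjusted over the list alone are named as well. Genes outside this rule are Egr1, Nppa, Nppb, Myh7, Myl4, the neighbours of Cavin4 other than Tmeff1, and genes added in the closing observations. Apart from the neighbours, which were taken by position, they were chosen without a rule fixed beforehand.

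The test was tried on simulated arrays with the means and spreads of the real probe sets, with 50 probe sets changed at each size. The filter kept 24889 probe sets, among them 49, 48, 42 and 41 of the changed ones, from the smallest change to the largest. Of these it recovered 38.8% of changes of 0.5 on the log2 scale, 66.7% of changes of 1, 95.2% of changes of 2 and 100% of changes of 3, with 5 false calls among 137. Of 40 simulated lists, the 1 whose 25 genes were shifted by 0.3 was called and 0 of the others were. Noise was drawn independently for each simulated probe set, so these lists could not show how shared variation between genes affects the calls. The estimated correlation within the real lists reached 0.657. The simulated shift was also larger than the mean change of any real list. Alternatives were quantile normalization, median centring, age as a covariate, the replicate number as a block, other filters, no intensity trend, array weights, the mean of a gene's probe sets, other region sizes and leaving out each array. After the data were seen, a test of the annotated probe sets alone and a test counting rows with identical values once were added. No other columns of values were present.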

Results

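Expression in the left ventricle of male mice was measured on 3 MURC knockout and 3 wild-type arrays, to find which transcripts differ when MURC is missing. The array medians were 4.60, 4.64 and 4.65 in the knockout and 4.71, 4.61 and 4.63 in the wild type, on the log2 scale. Arrays of the same genotype correlated between 0.987 and 0.989 over all probe sets, and arrays of different genotypes between 0.985 and 0.989. The labels number the samples and give their ages but do not state that each came from a separate animal, so p-values measure the spread between these samples.

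Cavin4, the targeted gene, was the transcript that separated the genotypes most clearly. Its signal fell from 8.48 ± 0.36 in the wild type to 5.57 ± 0.18 in the knockout (SD, n = 3), a log2 change of -2.91 (SE 0.18) or 7.52-fold, with an adjusted p of 0.012 in limma. The knockout arrays measured 5.38, 5.74 and 5.59 and the wild-type arrays 8.75, 8.62 and 8.07, so each array followed its label. A signal stayed in the knockout, at the 60.9th to 65.7th percentile of all probe sets on its array. Whether this probe set lies in the deleted part of the gene is not given in the sources used here. Without knockout replicate 1, knockout replicate 3 or wild-type replicate 1 the adjusted p was 0.0658, 0.119 and 0.0782, with log2 changes of -2.815, -2.92 and -2.775, and over all alternatives it ranged from 3.63e-06 to 0.119.

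**Figure D1:**
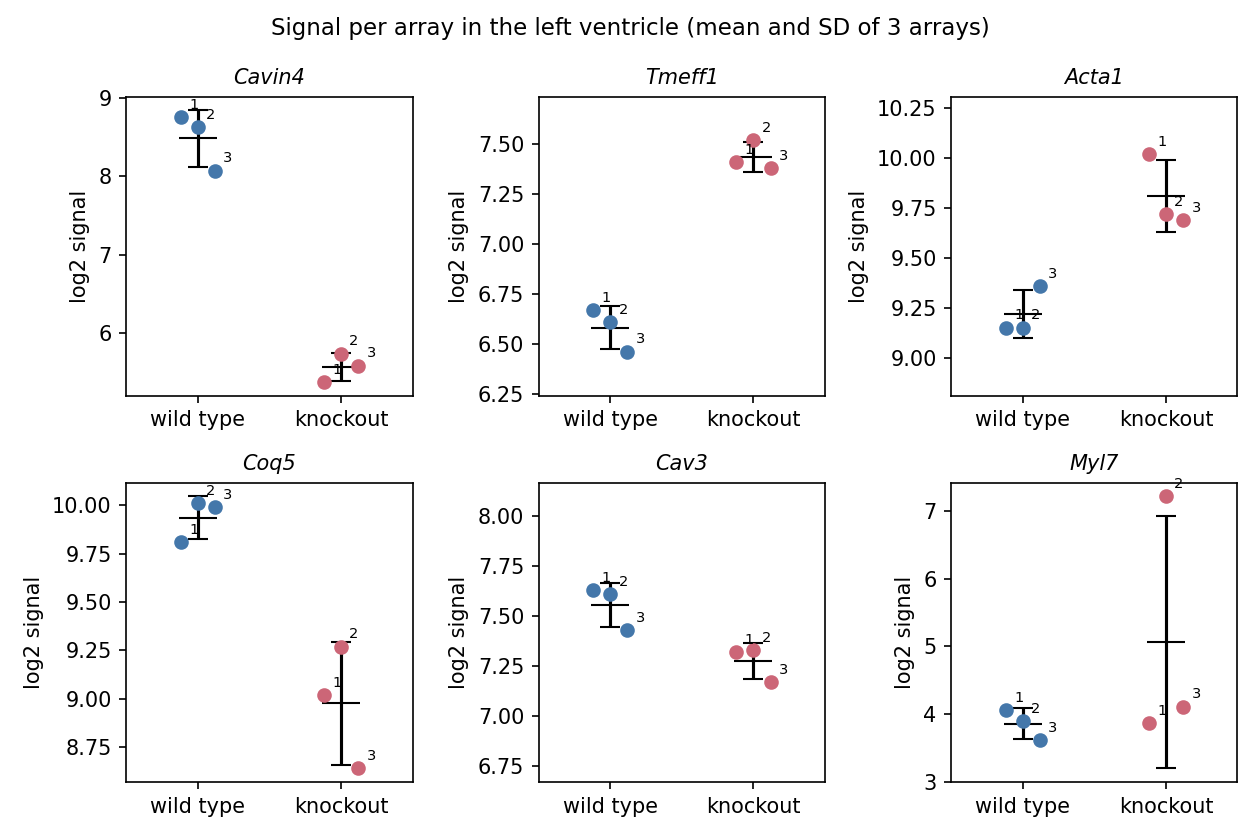
Log2 signal of 6 genes on each of the 6 arrays, with points numbered by replicate, horizontal marks for the mean of 3 arrays and bars for the SD. Each vertical axis has its own range and does not start at 0. Cavin4 lay between 5.38 and 5.74 in the knockout and between 8.07 and 8.75 in the wild type, Tmeff1, Acta1, Coq5 and Cav3 did not overlap between genotypes, and Myl7 was high in knockout replicate 2 alone.

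Beyond Cavin4, no probe set passed the adjusted threshold. Among the genes named by the rule, Tmeff1 and Acta1 had the smallest p of those with higher signal, and Acss1 of those with lower signal apart from Cavin4. Tmeff1, which encodes a transmembrane protein with follistatin-like domains, measured 7.44 ± 0.07 against 6.58 ± 0.11 (SD, n = 3), 0.86 higher on the log2 scale or 1.81-fold (limma adjusted p = 0.0606). Acta1, the skeletal muscle alpha-actin, measured 0.59 higher (SE 0.11, adjusted p = 0.0773). Among the lower signals, Acss1, a mitochondrial acetyl-CoA synthetase, measured a log2 change of -0.64, and Coq5, a methyltransferase of coenzyme Q synthesis, one of -0.96. Ccdc141, which encodes a coiled-coil protein, measured a change of -0.94, and 4 of its 5 probe sets did not overlap between genotypes.

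The other lower genes named by the rule were Creg1 at -0.68, Tmem50b at -0.61, Gatc at -0.63, Manea at -0.65, Uprt at -0.85, Alg6 at -0.63, Tmem159 at -0.71 and Ubxn2a at -0.82. A second Ubxn2a probe set measured only -0.21. Gatc encodes a subunit of the mitochondrial glutamyl-tRNA amidotransferase, Alg6 a glucosyltransferase of N-glycan assembly and Manea an endomannosidase. The other higher genes named by the rule were the minor spliceosomal RNA Rnu12 at 0.96, the vault RNA gene Vaultrc5 at 1.003, the Y-linked Srsy at 0.88 (18 probe sets without overlap, 15 of them with values of their own), the glutaredoxin gene Glrx3 at 0.67, the methyltransferase gene Inmt at 0.73 and the lipase inhibitor gene G0s2 at 0.62. The brightest Srsy probe set measured 5.37 in the knockout and 4.49 in the wild type, and probe sets of 1 gene are not separate evidence. Brox at 0.70 and Ppp4r2 at 0.94 completed the higher genes, and a second Brox probe set measured only 0.05. Both rested largely on a low wild-type replicate 1, without which they measured 0.35 and 0.39. Without knockout replicate 3 the second Brox probe set had the higher mean, and its change was 0.085. Judged by the probe set with the highest mean, 10 genes met the rule for higher signals, so fewer than 12 are named.

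Over 24898 probe sets, 1 passed the adjusted threshold in limma, that of Cavin4, and 0 were higher. At an unadjusted p under 0.05 there were 3417, of which 1172 were higher and 2245 lower, where chance alone would give 1245. With at least a 1.5-fold change as well, 321 were higher and 195 lower. Of these 516, 371 are not listed in the annotation, 67 have several symbols and 78 have 1 symbol, 33 of the last higher and 45 lower. Counting rows with identical values once, 228 were higher and 195 lower. The genotypes did not overlap at 4727 probe sets or 19.0%, where 10% is the share by chance. Of the probe sets with an unadjusted p under 0.05, 65.7% were lower as deposited, 51.2% after quantile normalization and 56.0% after median centring, and it was 50.2% without wild-type replicate 1. The share was 71.5% among annotated probe sets and 77.2% with the mean of a gene's probe sets, so it depended on the scaling, on 1 array and on the probe sets counted.

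The adjusted count depended on the processing. When only annotated probe sets were tested, a choice made after the data were seen, 361 passed, 123 higher and 238 lower, and quantile normalization gave 130. Of the 361, 238 have 1 symbol, with 48 higher and 190 lower, and 123 have several symbols. Rows with identical values occur in both kinds, and counting them once left 96 higher and 237 lower. Probe sets with several symbols, from which no gene is named, reached a higher log2 change of 1.93, above the 1.003 of Vaultrc5. All 11 lower genes named beside Cavin4 then passed among annotated probe sets, with adjusted p between 0.00344 and 0.012, against 0.00344 to 0.197 over all alternatives. Of the 10 higher genes 8 passed, from 0.00239 for Tmeff1 to 0.0334 for G0s2, while Brox had 0.159 and Ppp4r2 0.199, and over all alternatives the 10 ranged from 0.00158 to 0.785. The named genes were chosen by overlap, fold change and unadjusted p in the same arrays, so these passes are not separate evidence.

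The other proteins of caveolae were compared because Cavin4 is one of them. Cav3, the muscle caveolin, measured 7.27 ± 0.09 against 7.56 ± 0.11 (SD, n = 3), a log2 change of -0.28 (SE 0.08, limma adjusted p = 0.213). Ehd4, a membrane-remodelling ATPase, measured a change of -0.29 and the membrane-bending protein gene Pacsin2 one of -0.15, both without overlap. Values of Cav1, Cav2, Cavin1, Cavin2, Cavin3, Ehd1, Ehd2 and Pacsin3 overlapped between genotypes and differed by at most 0.09, and after quantile normalization the small changes of Cav2 and Cavin2 had the other sign. None of the 11 members passed over all probe sets or adjusted over the list alone, and 3 had an unadjusted p under 0.05. The list as a group had an adjusted p of 0.807 in camera.

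Of the 40 gene lists, 8 passed in camera with the preset correlation, 5 higher and 3 lower. Splits of the 6 arrays that mix the genotypes called from 0 to 8 lists, so the count itself does not set the genotypes apart. None of the 8 passed with an estimated correlation, where the smallest adjusted p over all lists was 0.65 and 1 list had an unadjusted p under 0.05. None passed in fry either, where the smallest adjusted p was 0.167 and 4 lists had an unadjusted p under 0.05. In fry's mixed test, which asks for change in either direction, 16 lists passed. That test does not compare a list with other genes, and 3417 of all 24898 probe sets had an unadjusted p under 0.05. The 16 therefore do not show change particular to these lists. Apart from Cavin4, which was left out of the lists, no list member passed over all probe sets, and 32 genes in 12 lists passed when adjusted over the list alone.

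**Figure D2:**
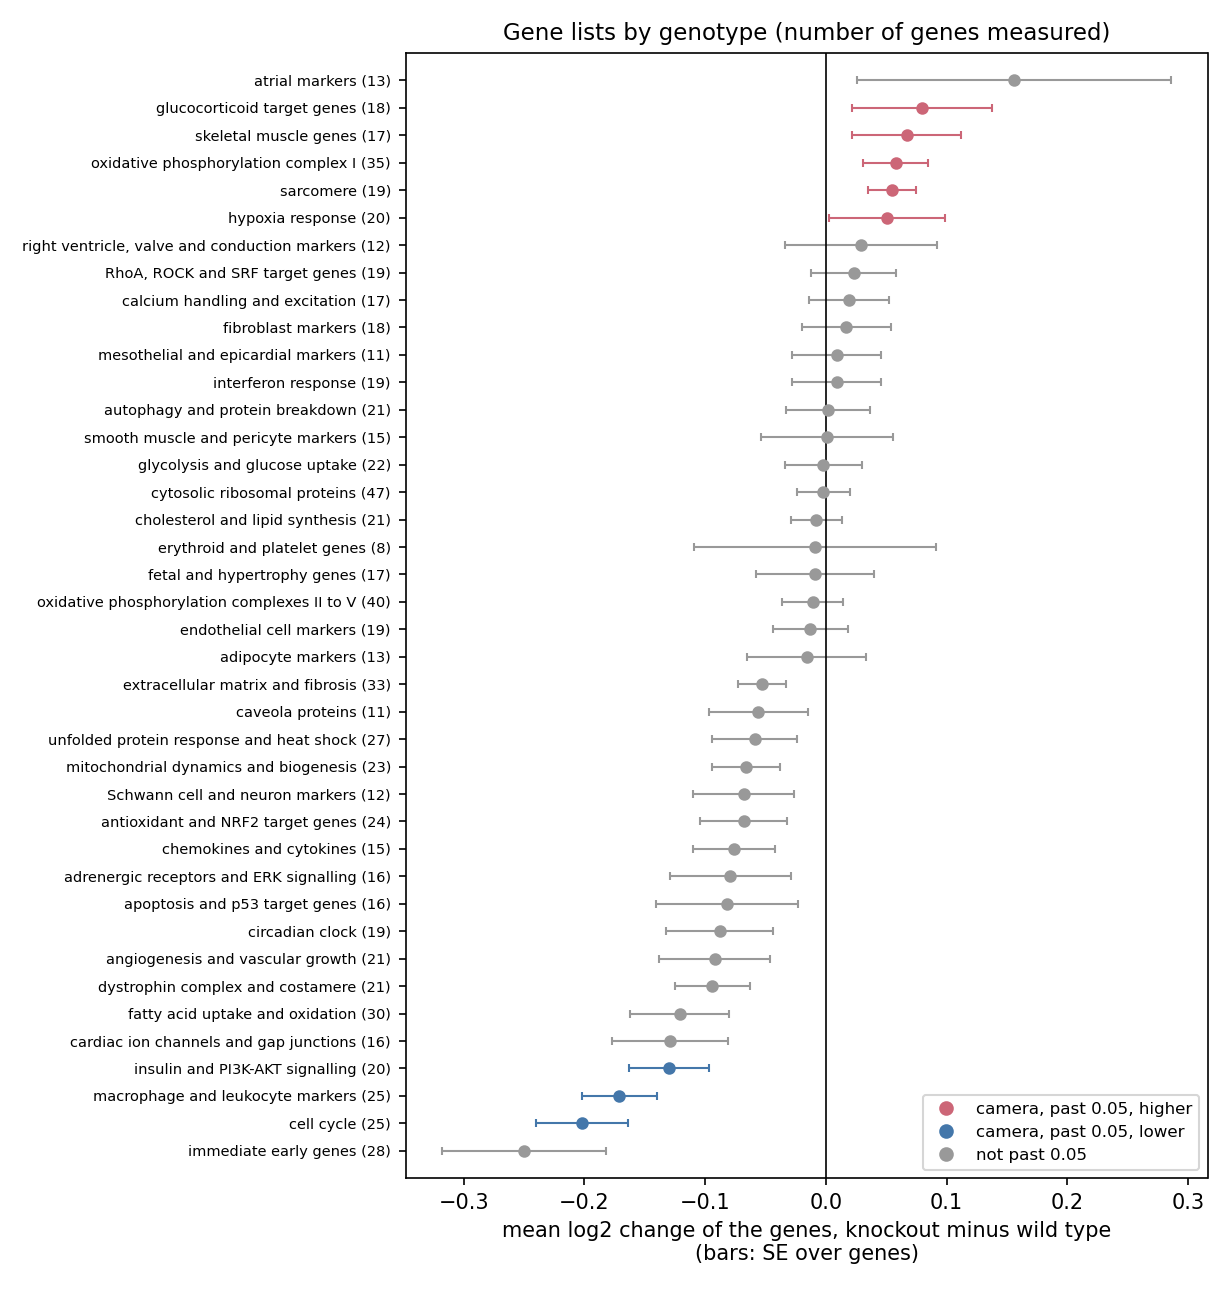
Mean log2 change of each of the 40 gene lists, knockout minus wild type, with bars for the SE over the genes of the list and the number of measured genes in brackets. Red and blue mark the 5 lists higher and the 3 lists lower past the adjusted threshold in camera with the preset correlation, none of which passed with an estimated correlation. Camera compares a list with all other genes, so a list can be called at a mean near 0.

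Genes of respiratory complex I, the first enzyme of the mitochondrial electron transport chain, were shifted higher as a list. Of 35 measured subunits 24 were higher and 11 lower, with a median log2 change of 0.10 (camera adjusted p = 0.000593, and adjusted p = 0.786 with an estimated correlation). The call held with each of the 6 arrays left out. Ndufa1, Ndufa5 and Ndufs5 measured 0.25, 0.33 and 0.28 higher, while Ndufs7 measured a change of -0.28. None passed adjusted over the list alone. Complexes II to V did not shift as a list (adjusted p = 0.539), yet 8 of 40 members passed adjusted over the list alone and 0 over all probe sets. Of these, Uqcr11 and Uqcrq of complex III were higher by 0.46 and 0.27, and the complex II gene Sdhd at -0.26, the cytochrome oxidase gene Cox8a at -0.23 and the ATP synthase genes Atp5g2, Atp5g1, Atp5d and Atp5c1 at -0.32, -0.31, -0.24 and -0.23 were lower.

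Muscle genes were shifted higher relative to other genes in 2 lists. In the sarcomere list, the contractile apparatus of heart muscle, 13 of 19 genes were higher with a median of 0.05 (camera adjusted p = 0.005, and adjusted p = 0.786 with an estimated correlation). Tcap and Myot, genes of the Z-disc, measured 0.18 and 0.17 higher, and the tropomyosin gene Tpm1 and the troponin gene Tnnc1 measured 0.14 and 0.16 higher. None of these passed adjusted over the list alone, and without wild-type replicate 3 the list's adjusted p was 0.0841. The skeletal muscle list had a median of 0.00 and a mean of 0.07, with 8 genes higher and 8 lower (adjusted p = 0.0348, and adjusted p = 0.65 with an estimated correlation). Acta1 alone passed adjusted over that list, and Ckm, Mybpc1 and Actn3 measured 0.13, 0.32 and 0.16 higher. That list's adjusted p was 0.0732 after quantile normalization and, without knockout replicate 2 or 3 or wild-type replicate 1 or 2, it was 0.0501, 0.14, 0.0704 and 0.0537.

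Cell cycle genes were lower, with 23 of 25 below the wild type and a median log2 change of -0.16 (camera adjusted p = 0.005, and adjusted p = 0.65 with an estimated correlation). The proliferation marker Mki67 and the topoisomerase gene Top2a measured changes of -0.69 and -0.72, and these 2 passed adjusted over the list alone. Both were dim. Mki67 measured 4.50 in the knockout and 5.19 in the wild type, and Top2a 3.43 and 4.15, where the filter stood at 3.45. Cdk2 and Tyms measured log2 changes of -0.37 and -0.36. Markers of macrophages and other leukocytes were lower as well, with 20 of 25 below the wild type and a median of -0.17 (adjusted p = 0.00907, and adjusted p = 0.786 with an estimated correlation). H2-Aa, an MHC class II gene, and C1qb, a complement gene of macrophages, measured -0.44 and -0.51 and passed adjusted over the list alone, and H2-Eb1 and H2-Ab1 measured -0.30 and -0.33. The cell cycle call ended without knockout replicate 2 (adjusted p = 0.0501) or wild-type replicate 2 (0.0658), with age as a covariate (0.0698) and with the stricter filter (0.0802), and the leukocyte call ended without knockout replicate 2 (0.127) or wild-type replicate 3 (0.52). In these settings the cell cycle mean was -0.18, -0.17, -0.17 and -0.18, against -0.20 in the main test. The leukocyte mean was -0.13 and -0.08, against -0.17.

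Genes of insulin and PI3K-AKT signalling were lower, with 17 of 20 below the wild type and a median of -0.12 (camera adjusted p = 0.0348, and adjusted p = 0.65 with an estimated correlation). Pdpk1, the kinase that activates AKT, measured a log2 change of -0.49 and was the 1 member past adjusted over the list alone. Gsk3a, the glucose transporter gene Slc2a4 and Irs2 measured -0.33, -0.17 and -0.37. The adjusted p was 0.0718 after quantile normalization, 0.0698 with age as a covariate, 0.0711 with the stricter filter and, without knockout replicate 1, 2 or 3 or wild-type replicate 2, 0.0536, 0.0501, 0.0666 and 0.133.

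Glucocorticoid target genes and hypoxia genes were shifted higher relative to other genes. In the glucocorticoid list 13 of 18 genes were higher with a median of 0.10 (camera adjusted p = 0.0132, and adjusted p = 0.786 with an estimated correlation). Ddit4, a stress-induced inhibitor of mTOR, measured 0.65 higher and Mertk 0.20 higher, while Angptl4 and Klf9 measured -0.58 and -0.14. In the hypoxia list 15 of 20 were higher with a median of 0.06 (adjusted p = 0.0393, and adjusted p = 0.65 with an estimated correlation), but the members with the smallest p besides Ddit4 were lower, namely the glucose transporter gene Slc2a1 at -0.28, Egln3 at -0.44 and Ldha at -0.13. None of these genes passed adjusted over either list alone. The glucocorticoid call ended without knockout replicate 3 (0.14), wild-type replicate 1 (0.2) or wild-type replicate 2 (0.481, mean -0.03) and with age as a covariate (0.0592), and the hypoxia call ended without knockout replicate 2 (0.0978), knockout replicate 3 (0.0826), wild-type replicate 1 (0.0704) or wild-type replicate 2 (0.171), with age as a covariate (0.179), without a filter (0.0646) and with the stricter filter (0.0711).

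The genes classically re-expressed in hypertrophy did not move as a list, with a mean of -0.01 and a camera adjusted p of 0.534. Acta1 passed adjusted over the list alone, and Xirp2 measured 0.22 higher, Actc1 -0.11 and Gata4 -0.28. The natriuretic peptide genes Nppa and Nppb and the fetal myosin gene Myh7 measured 0.11, -0.14 and -0.08, with overlapping genotypes. These directions rested on single arrays, since Nppa measured -0.11 without knockout replicate 2 and -0.01 without wild-type replicate 2. Without wild-type replicate 1, Nppb measured 0.05 and Myh7 0.37, without wild-type replicate 2 Nppb measured 0.13, and without wild-type replicate 3 they measured -0.60 and -0.57. The dystrophin complex and costamere list, which links the sarcomere to the membrane, had a mean of -0.09 (adjusted p = 0.172). Its members Sgcd, a sarcoglycan gene, and Dag1, the dystroglycan gene, measured -0.40 and -0.35 and passed adjusted over the list alone, and Sspn and Sgcb measured -0.38 and -0.17. Without wild-type replicate 3 that list had an adjusted p of 0.0355, within a range of 0.0355 to 0.786 over its alternatives.

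Fatty acid uptake and oxidation genes had a mean of -0.12 (camera adjusted p = 0.0679), and 3 of 30 passed adjusted over the list alone. These were the carnitine carrier gene Slc25a20 at -0.35 and the thioesterase genes Acot2 and Acot1 at -0.94 and -0.42, while Slc27a1 measured -0.27. The list had an adjusted p of 0.00992 with age as a covariate, 0.0336 without a filter and 0.00699 without knockout replicate 1, and at most 0.786 over its alternatives. Cardiac ion channels and gap junctions had a mean of -0.13 (adjusted p = 0.0666) with 14 of 16 below the wild type, including Kcnip2 at -0.43, Kcnj5 at -0.31 and Gja1, the connexin of ventricular gap junctions, at -0.24, while Kcna5 measured 0.43 higher. Its adjusted p was 0.0323 with age as a covariate, 0.0336 without a filter, 0.0323 with array weights and 0.0084 without wild-type replicate 1, and at most 0.65 over its alternatives. Genes of vascular growth had a mean of -0.09 (adjusted p = 0.577), with Fgf2, Vegfb, Apln and Pdgfa at -0.49, -0.55, -0.43 and -0.30, and these 4 passed adjusted over the list alone.

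In 3 more lists, members passed adjusted over the list alone although the list did not shift. In the apoptosis and p53 list (mean -0.08, camera adjusted p = 0.479) Ccng1, Mdm2, Sesn2 and Casp8 measured -0.31, -0.37, -0.31 and -0.27, and the survival gene Bcl2l1 measured 0.44 higher. In the unfolded protein and heat shock list (mean -0.06, adjusted p = 0.972) the small heat shock genes Hspb6 and Hspb7 measured -0.41 and -0.36, and Dnajb9 and Hsph1, which did not pass, measured -0.34 and 0.24. Among smooth muscle and pericyte markers (mean 0.00, adjusted p = 0.534) the smooth muscle myosin gene Myh11 measured 0.35 higher and the pericyte gene Abcc9 -0.30, and Tagln and Mcam, which did not pass, measured 0.42 and -0.25.

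Immediate early genes, which respond within minutes to stimulation and handling, had the lowest mean of the 40 lists, -0.25 (camera adjusted p = 0.0781), with a wide spread within the wild type. Fos measured 6.27, 6.07 and 4.83 in the 3 wild-type arrays and between 4.68 and 4.79 in the knockout. Egr1 measured 7.05, 6.89 and 5.44 in the wild type and between 5.38 and 5.61 in the knockout. Dusp1, Nr4a1 and Nr4a3 measured log2 changes of -0.39, -1.20 and -0.69. Without wild-type replicate 3 the list had an adjusted p of 8.6e-06, without knockout replicate 3 one of 0.00873, with array weights 0.0224 and without a filter 0.034. With age as a covariate the mean was -0.12 and the adjusted p 0.964, the highest over its alternatives.

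Atrial markers had a mean of 0.16 (camera adjusted p = 0.431), which rested on knockout replicate 2. In that array the atrial myosin light chain genes Myl7 and Myl4 measured 7.22 and 8.67, while the other 5 arrays lay between 3.61 and 4.11 for Myl7 and between 5.41 and 5.61 for Myl4. Without knockout replicate 2 the atrial list had a mean of -0.05, 2 probe sets passed the adjusted threshold over all probe sets and 3 of the 40 lists passed, and the atrial list did not pass in any alternative (adjusted p from 0.157 to 0.994).

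The lists of other cell types and processes not described above did not pass. The means were 0.02 for fibroblast markers (adjusted p = 0.219), 0.02 for RhoA, ROCK and SRF targets (0.292), 0.00 for autophagy and protein breakdown (0.292) and 0.03 for right ventricle, valve and conduction markers (0.321). Endothelial markers had a mean of -0.01 (0.431), interferon response genes 0.01 (0.431), cytosolic ribosomal proteins 0.00 (0.421) and mesothelial and epicardial markers 0.01 (0.479). Calcium handling genes had a mean of 0.02 (0.479), circadian clock genes -0.09 (0.479), cholesterol and lipid synthesis genes -0.01 (0.479) and mitochondrial dynamics and biogenesis genes -0.07 (0.479). The mean was 0.00 for glycolysis (0.52), -0.07 for antioxidant and NRF2 targets (0.577), -0.02 for adipocyte markers (0.588), -0.05 for extracellular matrix and fibrosis (0.625) and -0.07 for Schwann cell and neuron markers (0.665). Adrenergic and ERK signalling genes had a mean of -0.08 (0.807), chemokines and cytokines -0.08 (0.825) and erythroid and platelet genes -0.01 (0.916). Without wild-type replicate 1 the ribosomal and endothelial lists passed as higher (0.00293 and 0.027), and without wild-type replicate 3 the interferon list did (1.38e-07). Over the alternatives these 3 lists reached 0.994 in fry, which does not compare a list with other genes. In 14 lists the median, mean and test differed in sign or 1 of them was 0, all of them tested as higher, since camera compares with all other genes and the median log2 change of the tested probe sets was -0.04. Skeletal muscle was the 1 called list among these 14.

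Genes near Cavin4 were compared because DNA around a targeted gene can come from another strain than the rest of the genome. Tmeff1 is the nearest measured gene on one side of Cavin4 in GRCm38.p6. The next genes on that side, Msantd3, Tex10 and Invs, differed by at most 0.01. On the other side Plppr1, Acnat2 and Acnat1 measured 0.11, 0.05 and -0.25 with overlapping genotypes, and Mrpl50 measured -0.23 (limma unadjusted p = 0.0394). Within 10 Mb, 21 of 147 genes or 14.3% had an unadjusted p under 0.05, against 1725 of 15100 or 11.4% elsewhere. The odds ratio was 1.29 with a 95% interval of 0.771 to 2.07 (Fisher's exact test, two-sided, p = 0.296), and it was 0.559 within 5 Mb and 1.08 within 20 Mb.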

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

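The tests of annotated probe sets alone and of identical rows counted once were chosen after the data were seen. Cavin4 stayed lower in every alternative tried, between -3.12 and -2.78 with single arrays left out, and lost the adjusted threshold without knockout replicate 1, knockout replicate 3 or wild-type replicate 1. The replicate numbers did not pair the samples, since deviations of same-numbered arrays correlated at -0.059, 0.021 and -0.057 and only number 2 matched its own number best. With the replicate block Cavin4 kept a log2 change of -2.91 with an adjusted p of 0.0754, 0 probe sets passed in limma and 3257 had an unadjusted p under 0.05, where the block leaves fewer degrees of freedom. With that block the ion channel, fatty acid and immediate early lists passed, with adjusted p of 0.049, 0.049 and 0.0416. Against 1 in the main test, the count past the adjusted threshold was 130 after quantile normalization, 105 after median centring, 34 with age as a covariate, 48 with the 50th percentile filter, 126 with array weights, 118 with the mean of a gene's probe sets, 361 among annotated probe sets and 0 to 12 with single arrays left out. The 0 came without knockout replicate 1, knockout replicate 3 or wild-type replicate 1, with 2867, 2310 and 3114 at an unadjusted p under 0.05, and the 12 without wild-type replicate 2. The main test sat just above the threshold, with 171 probe sets at an adjusted p between 0.05 and 0.07. Among annotated probe sets the prior degrees of freedom of limma rose from 3.44 to 7.51 and the median residual SD fell from 0.129 to 0.114, since the unlisted probe sets vary more (0.211). The number of probe sets tested fell at the same time, and the parts of spread and number of tests in the 361 were not separated. The causes of the other differences were not tested. Larger changes without adjustment numbered 516, and 787 without a filter, 244 with the 50th percentile filter, 51 with the mean of a gene's probe sets and 148 among annotated probe sets. The causes of these differences were not tested. The 8 called lists were 5 with the 50th percentile filter, 0 with an estimated correlation, 0 in fry, and 3 to 9 with single arrays left out, with 3 without knockout replicate 2 or wild-type replicate 2. The odds ratio near Cavin4 passed the threshold in no alternative. Of the named genes' values under alternatives, 2970 kept their side of the threshold, 88 passed only there and 4 passed only in the main test, and of the lists' values 694, 18 and 46. With the 50th percentile filter the mesothelial and Schwann cell lists had too few genes for a value. Other pseudocounts did not apply to a table already on the log2 scale. Signal over background is unknown, since detection values were not used here.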

Other observations

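The tests below were all chosen after the results they bear on were seen, and the genes of the first paragraph were chosen after their values were seen. Among annotated probe sets, Trdn was the 1 gene of 809 with several probe sets that passed in both directions. Trdn encodes triadin, a protein of the calcium release complex of heart muscle. Of its 17 probe sets, 2 were higher, at log2 changes of 0.51 and 0.40, and 3 were lower, at -0.59, -0.51 and -0.42, with adjusted p between 0.00674 and 0.0324. These 5 had adjusted p between 0.0614 and 0.118 when all probe sets were tested. The probe set with the highest signal measured -0.13 with overlapping genotypes. Jph1, a junctophilin gene, measured -0.61, the choline phosphotransferase gene Chpt1 -0.52, the annexin gene Anxa11 -0.44 and the kinetochore gene Cenpf -0.52, with adjusted p from 0.00429 to 0.0197 among annotated probe sets and from 0.0606 to 0.0721 among all. The Jph1 value is not from the gene's probe set with the highest mean, which did not meet the rule for named genes.

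Small nucleolar RNAs, which guide chemical changes of ribosomal RNA, were higher in the knockout at 45 of 51 distinct probe sets, with a median log2 change of 0.15. Protein-coding probe sets had a median of -0.04 and microRNA probe sets, at a lower signal, one of -0.07. Snora74a measured 0.97 higher and Rpph1, the RNA of ribonuclease P, 0.51 higher, while Rmrp and Rn7sk measured 0.08 and -0.01 with overlapping genotypes, and Terc, the telomerase RNA, measured -0.23 without overlap. None of these passed the adjusted threshold over all probe sets in limma. 4 small nucleolar RNA probe sets were higher and 0 lower at an unadjusted p under 0.05.

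Other probe sets of similar signal did not show the shift of the small nucleolar RNAs. The class median stood at percentile 100 among 10000 random lists of the same size and signal, whose middle 95% lay between -0.09 and 0.01. Members of those lists were drawn independently, so a class whose members vary together can fall outside them without an effect of genotype. The class median stayed above 0 after quantile normalization (0.17) and median centring (0.17) and with each array left out (0.07 to 0.26). The class mean ranged by up to 0.345 among arrays of the same genotype, more than the 0.157 between genotypes, and the exact permutation p was 0.3, where 0.1 is the smallest that 3 against 3 allows. Sample-to-sample differences in the class may therefore account for the shift, and their source was not tested. An effect of genotype stays open and was not tested apart from these.

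Tmeff1 measured 1.81-fold higher next to the targeted gene, with no such difference in the next 3 genes on its side. The ages of the groups do not account for it as the whole cause, since its log2 change was 0.859 with age as a covariate (95% interval 0.603 to 1.11). An offset between the arrays does not account for it either, with 0.906 after quantile normalization (0.742 to 1.07). Linked DNA of a donor strain over the surrounding region cannot be told apart from other causes, because the odds ratio of 1.293 within 10 Mb had an interval that includes both 1 and 2. A direct effect of the targeted allele on its neighbour is a candidate explanation that these arrays did not test.

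Myl7 and Myl4 were high in knockout replicate 2 alone, by 3.31 and 3.16 over the mean of the other 5 arrays. A brighter array does not account for it, since the median of that array was 4.64 against 4.60 to 4.71 in the others. Of the other atrial markers, 5 of 11 were highest there and at most 2 in any other array, and of the hypertrophy list 0 of 16 genes outside the atrial list were highest there. Nppa, which stands in both lists, measured 11.44 against 10.67 to 11.13. Some atrial tissue in the sample and fetal gene expression are candidate explanations that cannot be told apart, because genes of 1 array are not independent and 6 arrays are too few. Of the 15 atrial markers written for the list 13 were measured, and 5 of these also stand in another list. Only genes that passed the signal filter count as measured, so the 13 say nothing about how many atrial markers pass it.

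The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. For probe sets past the adjusted threshold, 1 split reached the real count of 1, the real split itself, and the highest other count in limma was 0, where the other splits had 671 to 1223 probe sets at an unadjusted p under 0.05. For larger changes without adjustment, 1 split reached the real 516, and the highest other count was 278. For gene lists past the threshold, 3 splits reached the real 8, and the highest other count was 8. The splits that mix the genotypes called 6, 4, 8, 5, 0, 6, 5, 3 and 8 lists.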
